A study of Homo sapiens with 28 samples.

How the data were processed

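The deposited files hold raw gene counts, 1 column per library, for 28 libraries of HT-1080 cells in 7 groups of 4. The authors made these counts from total RNA, and per the labels sequenced on an Illumina instrument. Per the submitters' processing notes, HISAT, SAMtools, featureCounts and DESeq2 were used with the build hg38, with no versions, annotation or strand setting stated. The doses in the design text are in µM for the fatty acids, while sample labels write mM, and µM is used here. Cells were treated overnight, and the design text calls the 4 replicates of a group independent. Samples with LA alone and CLA18:2 alone are listed later in the series, and the labels give no batch.

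Genes are named by the symbols of the deposited table. Library totals ran from 16226270 to 24286824 counts. Genes were kept with the default filter of edgeR on the 7 groups, which left 16325 of 60286 genes holding 99.9% of counts. Counts were scaled by the trimmed mean of M values (TMM), and a model with 1 mean per group was fitted to all 28 libraries with edgeR 4.0.16 in R 4.3.3. Contrasts were tested by its quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Each SE was approximated as the size of the log2 fold change divided by the square root of F, and the interval is at 95%. CPM are counts scaled by library total and TMM factor. Detected genes at a common total were counted after thinning each library to 16226270 counts. Intervals on a single library's share are Wilson 95% intervals and cover counting error only. Positions are from GENCODE release 29 on GRCh38, in which 280 of 296 named genes matched once. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

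The 12 comparisons set each treatment against DMSO, each combination against its parts, and the isomers against each other at the same dose. The 3 interactions ask whether the response to RSL3 differed with LA, with CLA18:2, or between the isomers. CLA18:3 was given at another dose and no combination with RSL3, so it was compared with DMSO alone. The groups, comparisons, lists and the rule for named genes were chosen before the data were examined. Named genes are 35 fixed genes, of which 33 could be tested, the 10 largest changes each way, and 4 members with the smallest p of each list past its test. For the largest changes the groups' libraries may not overlap and mean CPM over all 28 libraries is at least 2, and in interactions 5 each way were taken without the overlap condition. Lists were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Results for 1 of the fixed genes are not reported here. Adjustment over the list alone means Benjamini-Hochberg over its members.

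The 29 lists were NRF2 targets, ATF4 and integrated stress response genes, ER unfolded protein response genes, cytosolic heat shock genes, metallothioneins, aldehyde and electrophile detoxification genes, ferroptosis regulators, selenoproteins, cholesterol synthesis and SREBP2 target genes, fatty acid synthesis and desaturation genes, PPAR targets and fatty acid oxidation genes, lipid droplet and triacylglycerol synthesis genes, LXR targets, p53 targets, mitotic and proliferation genes, DNA replication genes, NF-kappaB and cytokine genes, immediate early and AP-1 genes, type I interferon response genes, hypoxia and HIF1 targets, extracellular matrix and adhesion genes, lysosome and autophagy genes, cytosolic ribosomal protein genes, nuclear-encoded respiratory chain genes, mitochondrially encoded mRNAs, replication-dependent histone genes, epithelial cell markers, blood cell markers, and hepatocyte and kidney markers. The last had 2 expressed members of 14 and was not tested as a set. Correlations between responses that share DMSO were set against 20 simulations of unchanged groups, drawn with the dispersion of each group, and against 3 splits that give each response its own DMSO libraries. Simulations with pooled dispersions overstated the covariance that shared DMSO libraries add, as estimated from those splits. Dispersions per group were therefore taken, after 2 other constructions, for matching that covariance, not for the correlations.

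The replicate numbers were not used as pairs. Of 84 correlations of residuals between same-numbered libraries, 30 exceeded 0.1, with a median of 0.0123 and a range of -0.433 to 0.451. Of 21 group pairs, RSL3 with RSL3+CLA18:2 exceeded 0.1 in all 4 numbers, at 0.160, 0.114, 0.223 and 0.418. Replicate pairs had a chi-square per degree of freedom from 2.42 to 27.8 in 42 pairs, above what sequencing 1 library again would give, while repeat preparations of a culture were not tested.

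The method was tested on simulated RSL3 against DMSO with 50 of 16325 genes changed at each fold. It recovered 56% at 1.25-fold, 70% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 8 false calls of 16098 unchanged genes. A simulated LA against DMSO with no change gave 0 calls in edgeR. A shift of 0.2 in 29 members of a list had adjusted p = 2.1e-15, and 0 of 18 untouched lists were called.

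Alternatives planned were RLE scaling, DESeq2 1.42.0, no low-count filter, a replicate block, a fit of only the groups compared, each library left out, and the estimated correlation. Added after seeing the data were fits without the libraries under 20000 detected genes, without those under 0.8% mitochondrial mRNA, limma voom with quality weights, and DESeq2 without independent filtering. The last was added because the default filtering left out 12976 genes in RSL3+LA against LA and 15508 in the interaction of RSL3 with LA.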

Results

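RNA of HT-1080 cells, a human fibrosarcoma line, was sequenced in 28 libraries, 4 in each of 7 groups. The groups were vehicle (DMSO), 10 nM RSL3, 80 µM linoleic acid (LA), 80 µM conjugated linoleic acid (CLA18:2), RSL3 with LA, RSL3 with CLA18:2, and 5 µM CLA18:3, a conjugated acid with 3 double bonds. RSL3 is an inhibitor of GPX4, the enzyme that reduces lipid hydroperoxides in membranes, and its use induces ferroptosis, a cell death driven by lipid peroxidation. LA and CLA18:2 are isomers with 18 carbons and 2 double bonds, which are conjugated in CLA18:2 and separated by a methylene group in LA. Tests took 16325 of 60286 listed genes. The first principal component held 20.2% of the variance and the second 8.96%. Values below are log2 fold changes ± SE with n = 4 libraries per group. Benjamini-Hochberg adjusted p values are from edgeR quasi-likelihood tests for genes and camera for lists. With 4 cultures per group, called independent in the series text, p values measure only the spread pooled over these 28 libraries. They may be too small for RSL3+CLA18:2 and CLA18:3, with wider spread, and too large for DMSO.

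Genes with a count in CLA18:3 libraries numbered 19378 ± 801 at a common total (SD, n = 4), and 20015 ± 1119.6 in RSL3+CLA18:2 libraries, against 22745 ± 109 in DMSO. Mitochondrially encoded mRNAs took 1.40 ± 0.101% of counts in DMSO and 1.65 ± 0.202% in RSL3+LA. Their share was 1.2 ± 0.47% in RSL3, 1.21 ± 0.601% in CLA18:3 and 1.03 ± 0.421% in LA. It was 0.806 ± 0.544% in CLA18:2 and 0.640 ± 0.692% in RSL3+CLA18:2, where 1 library reached 1.68%. Marker lists of other cell types had few expressed members, 5 of 16 for epithelial cells, 4 of 16 for blood cells and 2 of 14 for hepatocytes and kidney epithelium, and the last was too small to test. No epithelial or blood cell list passed the test in any comparison. The biological coefficient of variation was 4.50% in DMSO, 7.78% in RSL3, 7.32% in LA, 8.93% in CLA18:2, 9.01% in RSL3+LA, 15.3% in RSL3+CLA18:2 and 20.0% in CLA18:3.

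**Figure D1:**
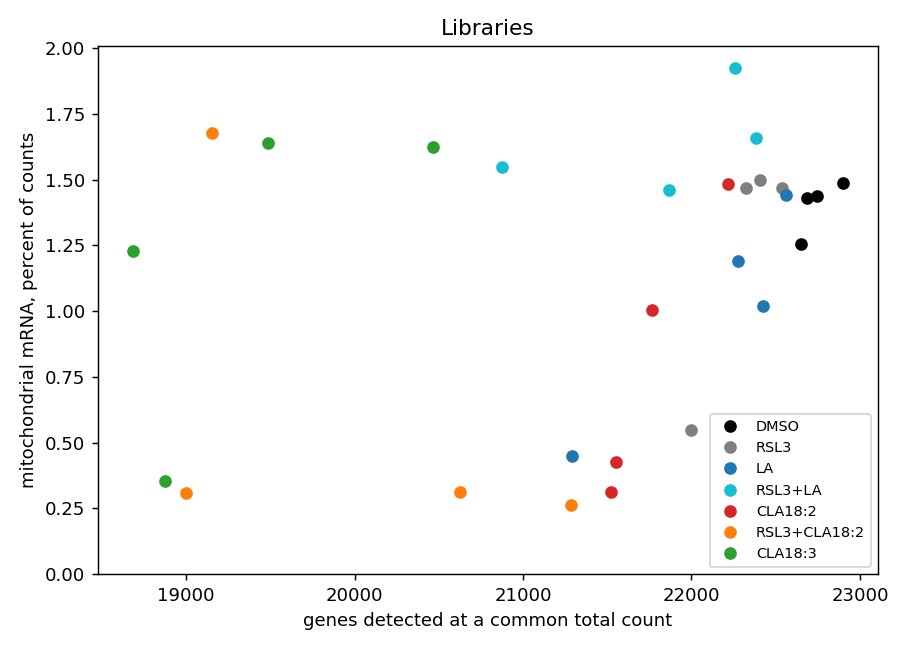
Each point is a library, with the genes detected at a common total on the horizontal axis and the percent of counts from mitochondrial mRNAs on the vertical axis. CLA18:3 libraries lie between 18686 and 20465 genes and DMSO libraries between 22651 and 22897.

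The lead genes are protein-coding in GENCODE release 29 on GRCh38. They are HMOX1 on chromosome 22 from 35380361 to 35394214, SLC7A11 on chromosome 4 from 138164097 to 138242349, GCNT3 on chromosome 15 from 59594875 to 59640239 and FOS on chromosome 14 from 75278774 to 75282230. Further lead genes are CPT1A on chromosome 11 from 68754620 to 68844410, HMGCS1 on chromosome 5 from 43289395 to 43313512, DDIT3 on chromosome 12 from 57516588 to 57521737, CXCL8 on chromosome 4 from 73740506 to 73743716 and GPX4 on chromosome 19 from 1103926 to 1106791. In DMSO, normalized levels (CPM, mean ± SD, n = 4) were 26.9 ± 2.23 for HMOX1, 18.7 ± 1.49 for SLC7A11, 9.69 ± 1.17 for CPT1A, 207 ± 2.69 for HMGCS1 and 80.8 ± 3.44 for GPX4. PLIN2, ANGPTL4 and ASNS lay close to the detection floor, so folds for them are rough. Also rough are folds over the DMSO means of GCNT3 (0.146 CPM), AKR1C1 (0.262), AKR1B10 (0.377) and FOS (0.477). PDK4 and HSPA1A had too few counts to test.

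**Figure D2:**
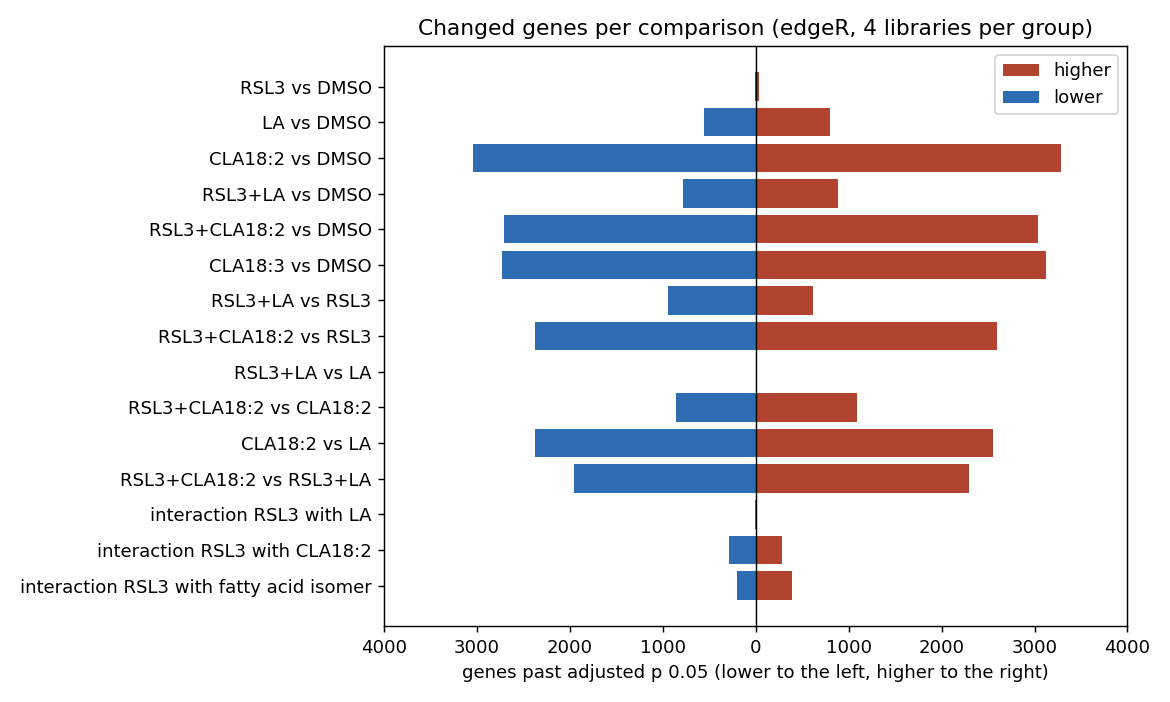
Bars show the number of genes past the test in each comparison, lower to the left and higher to the right. They run from 4 genes in the interaction of RSL3 with LA to 6329 genes in CLA18:2 against DMSO.

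RSL3 against DMSO asks what the GPX4 inhibitor alone changed at this dose. HMOX1, which degrades heme and releases iron, rose by 2.30 ± 0.11, adjusted p = 1.3e-16, to 124 to 156 CPM from 24.4 to 29.8 in DMSO. The AP-1 genes FOS (3.23 ± 0.27, adjusted p = 8.4e-10), FOSB (1.24 ± 0.17) and ATF3 (0.84 ± 0.08) rose, as did SLC7A11, the cystine importer (0.93 ± 0.10), and the interleukin 8 gene CXCL8 (1.06 ± 0.18). DDIT4, an inhibitor of mTORC1, rose by 1.57 ± 0.17, OSGIN1 by 0.67 ± 0.09, and PPP1R15A, which reverses eIF2alpha phosphorylation, by 0.37 ± 0.05. AKR1C1, an aldo-keto reductase, rose by 2.14 ± 0.37 and the heat shock gene HSPA6 by 1.99 ± 0.20, but both have close paralogs, so shared reads leave their identity uncertain. GPX4 itself was not past the test, at 0.00 (95% interval -0.15 to 0.14). 9 of 29 NRF2 targets rose and 0 fell (18 and 0 adjusted over the list alone, adjusted p = 3.3e-53), among them TXNRD1 (0.30 ± 0.05), GCLM (0.39 ± 0.07) and the ferritin gene FTL (0.35 ± 0.05). Among 29 ATF4 and integrated stress response genes, 3 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 1.2e-20). For ferroptosis regulators, 5 of 41 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 4.2e-16). HMOX1, SLC7A11, FTL and TXNRD1 are also NRF2 targets, and lists sharing genes are not independent. Of the 23 immediate early and AP-1 genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 3.6e-15). 2 of 29 lysosome and autophagy genes rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 1.2e-05), with SQSTM1, an autophagy receptor, at 0.43 ± 0.05. Among 31 DNA replication genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, adjusted p = 2.5e-04), with a median of 0.07. Among further lists past the test, with members higher and lower and then adjusted over the list alone, were ER unfolded protein response genes (1 and 0 of 21, 8 and 0, adjusted p = 2.9e-06), cytosolic heat shock genes (1 and 0 of 17, 7 and 1, adjusted p = 2.0e-05) and NF-kappaB and cytokine genes (1 and 0 of 17, 3 and 1, adjusted p = 2.0e-05), all up. Of 28 lists, 13 passed, 12 higher and 1 lower, 11 of them also with an estimated correlation. With RSL3 and DMSO, detected genes numbered 22316 ± 230.3 and 22745 ± 109, and the mitochondrial share was 1.2 ± 0.47% and 1.40 ± 0.101%. RSL3 replicate 4 set the top of the HMOX1 range, at 156 CPM against 124 to 126 in the other RSL3 libraries, and had 0.548% mitochondrial mRNA against 1.47 to 1.5%. Without it HMOX1 rose by 2.21. Adjusted p reached 0.940 in the 15 lists that did not pass. Among these, with members higher and lower over all genes and then adjusted over the list alone, were lipid droplet and triacylglycerol synthesis genes (0 and 0 of 18, 0 and 0, adjusted p = 0.837), LXR targets (0 and 0 of 9, 0 and 0, adjusted p = 0.158), extracellular matrix and adhesion genes (0 and 1 of 31, 4 and 1, adjusted p = 0.115) and mitochondrially encoded mRNAs (0 and 0 of 13, 0 and 0, adjusted p = 0.108). So were replication-dependent histone genes (0 and 0 of 15, 0 and 0, adjusted p = 0.115), epithelial cell markers (0 and 0 of 5, 0 and 0, adjusted p = 0.390) and blood cell markers (0 and 0 of 4, 0 and 0, adjusted p = 0.149).

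RSL3 changed 33 genes, 29 higher and 4 lower, of which 10 changed at least 2-fold, and 989 passed without adjustment. DESeq2 gave 66 (51 higher, 15 lower), and 53 (41 higher, 12 lower) without its independent filtering. The count was 112 with no low-count filter, 150 (109 higher, 41 lower) with limma voom, and 20 without DMSO replicate 3. The lower genes encode 2 collagens, a LIM domain protein and an actin-binding adaptor, and each depends on single libraries: COL10A1 (-0.64 ± 0.14, adjusted p = 0.0239, adjusted p 0.0728 to 0.158 without each of DMSO replicates 3 and 4 and RSL3 replicates 1 and 3), LMCD1 (-0.49 ± 0.11, adjusted p = 0.0269, adjusted p 0.0676 to 0.133 without each of DMSO replicates 2, 3 and 4 and RSL3 replicates 1, 2, 3 and 4), COL1A1 (-0.39 ± 0.08, adjusted p = 0.0250, adjusted p 0.0869 to 0.135 without each of DMSO replicates 2, 3 and 4 and RSL3 replicates 3 and 4) and EPS8L2 (-0.30 ± 0.06, adjusted p = 0.0269, adjusted p 0.0640 to 0.101 without each of DMSO replicates 2 and 3 and RSL3 replicates 1, 3 and 4). FTH1, the ferritin heavy chain, rose by 0.39 ± 0.08 with adjusted p 0.0602 to 0.111 without each of DMSO replicates 3 and 4 and RSL3 replicate 1. GCNT3, a mucin-type glycosyltransferase, rose by 2.10 ± 0.40 with adjusted p 0.0530 to 0.0906 without each of DMSO replicates 3 and 4 and RSL3 replicates 1 and 2.

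LA against DMSO asks what the unconjugated acid alone changed. CPT1A, which starts mitochondrial import of fatty acids, rose by 2.18 ± 0.09, adjusted p = 6.9e-19, to 40.7 to 48.1 CPM from 8.48 to 11.3. Its partners in oxidation rose too, with the carnitine carrier SLC25A20 at 1.29 ± 0.12, the thiolase ACAA2 at 0.99 ± 0.06 and the isomerase ECH1 at 0.78 ± 0.08. HMOX1 rose by 0.99 ± 0.11, SLC7A11 by 0.77 ± 0.10 and RNF145, a ubiquitin ligase of the endoplasmic reticulum (ER), by 1.24 ± 0.05, adjusted p = 6.9e-19. The sterol genes HMGCS1 (-0.67 ± 0.05, adjusted p = 6.5e-12), ACAT2 (-0.72 ± 0.06) and INSIG1 (-0.42 ± 0.04) fell, as did SCD, the delta-9 desaturase (-0.58 ± 0.04), ATF3 (-0.50 ± 0.09), the growth factor gene TGFB2 (-1.06 ± 0.11) and EDN1, the endothelin gene (-1.07 ± 0.10). For PPAR targets and fatty acid oxidation genes, 10 of 30 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 3.0e-15). Of the 24 cholesterol synthesis and SREBP2 target genes, 0 rose and 16 fell (0 and 18 adjusted over the list alone, adjusted p = 1.1e-28), with DHCR7 at -0.43 ± 0.05. 15 of 29 NRF2 targets rose and 0 fell (19 and 0 adjusted over the list alone, adjusted p = 6.4e-20), with NQO1 at 0.43 ± 0.06 and FTL at 0.57 ± 0.05. Among 29 ATF4 and integrated stress response genes, 7 rose and 3 fell (10 and 3 adjusted over the list alone, adjusted p = 2.2e-04), with GDF15, a stress cytokine, at 0.82 ± 0.06. For ER unfolded protein response genes, 11 of 21 rose and 0 fell (14 and 0 adjusted over the list alone, adjusted p = 4.0e-09), with the chaperone HSPA5 at 0.34 ± 0.03. Of the 26 hypoxia and HIF1 targets, 13 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted p = 1.6e-07), with VEGFA at 0.61 ± 0.07. The test also called metallothioneins (2 and 0 of 4 higher and lower, 2 and 0 adjusted over the list alone, adjusted p = 0.00158, up), DNA replication genes (0 and 5 of 31 higher and lower, 0 and 9 adjusted over the list alone, adjusted p = 4.0e-06, down) and lysosome and autophagy genes (6 and 0 of 29 higher and lower, 6 and 0 adjusted over the list alone, adjusted p = 2.2e-04, up). In all 16 of 28 lists passed (10 higher, 6 lower), and 10 held with an estimated correlation. Libraries of LA held 1.03 ± 0.421% mitochondrial mRNA and 22138 ± 577 detected genes, those of DMSO 1.40 ± 0.101% and 22745 ± 109. Mitochondrially encoded mRNAs were as a list lower (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 0.0298, adjusted p = 0.592 with an estimated correlation, adjusted p 0.323 without LA replicate 4). LA changed 1358 genes, 801 higher and 557 lower, 56 of them at least 2-fold. The count was 2394 when only these groups were fitted and 2803 with limma voom.

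CLA18:2 against DMSO asks the same of the conjugated isomer. HMOX1 rose by 3.57 ± 0.11, adjusted p = 2.4e-23, to 291 to 375 CPM from 24.4 to 29.8, and SLC7A11 by 3.40 ± 0.09, adjusted p = 1.2e-24. GCNT3 rose by 7.11 ± 0.27 from 1 to 5 counts per DMSO library, so its fold is rough, and increases followed for AKR1B10, a reductase of lipid aldehydes (5.08 ± 0.30), CXCL8 (4.10 ± 0.16) and OSGIN1 (3.26 ± 0.08). AIFM2, which encodes the ubiquinone reductase FSP1 that protects from ferroptosis, rose by 1.67 ± 0.08, whereas GPX4 was not past the test, at 0.00 (95% interval -0.15 to 0.14). DDIT3, the stress factor CHOP, rose by 2.03 ± 0.15, and SQSTM1 by 2.75 ± 0.05. TGFB2 (-2.30 ± 0.12), the matrix gene THBS1 (-2.02 ± 0.07) and SCD (-1.59 ± 0.05, adjusted p = 3.8e-24) fell. 29 of 29 NRF2 targets rose and 0 fell (29 and 0 adjusted over the list alone, adjusted p = 9.0e-76), with GCLM at 1.69 ± 0.07, TXNRD1 at 1.26 ± 0.05 and FTL at 1.76 ± 0.05. Among 24 cholesterol synthesis and SREBP2 target genes, 0 rose and 23 fell (0 and 23 adjusted over the list alone, adjusted p = 6.9e-28), with HMGCS1 at -1.27 ± 0.05 and INSIG1 at -1.28 ± 0.05. For mitotic and proliferation genes, 0 of 25 rose and 23 fell (0 and 23 adjusted over the list alone, adjusted p = 4.1e-17), with cyclin gene CCNA2 at -0.84 ± 0.05 and CDC20 at -0.67 ± 0.04. Of the 31 DNA replication genes, 0 rose and 29 fell (0 and 29 adjusted over the list alone, adjusted p = 4.8e-22), with CDC6 at -0.78 ± 0.04 and UHRF1 at -0.98 ± 0.06. 20 of 21 ER unfolded protein response genes rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p = 9.7e-23), with HSPA5 at 1.33 ± 0.03 and HERPUD1 at 1.15 ± 0.06. Among 29 lysosome and autophagy genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone, adjusted p = 2.1e-21), with the protease gene CTSD at 1.61 ± 0.05. For PPAR targets and fatty acid oxidation genes, 16 of 30 rose and 4 fell (16 and 6 adjusted over the list alone, adjusted p = 1.3e-05), with CPT1A at 2.53 ± 0.09. Of the 29 ATF4 and integrated stress response genes, 24 rose and 2 fell (24 and 2 adjusted over the list alone, adjusted p = 4.3e-14), with SESN2 at 1.05 ± 0.06 and TRIB3 at 0.86 ± 0.06. Past the test, too, with members higher and lower and then adjusted over the list alone, were aldehyde and electrophile detoxification genes (12 and 1 of 19, 12 and 1, adjusted p = 2.0e-07), selenoproteins (10 and 4 of 19, 10 and 5, adjusted p = 0.00171) and ferroptosis regulators (19 and 9 of 41, 19 and 9, adjusted p = 3.2e-09), all up. The lists past the test numbered 17 of 28, 13 higher and 4 lower, with 14 left under an estimated correlation. Mitochondrial mRNA took 0.806 ± 0.544% of counts in CLA18:2 and 1.40 ± 0.101% in DMSO, with 21764 ± 320.3 and 22745 ± 109 detected genes. CLA18:2 changed 6329 genes, 3285 higher and 3044 lower, and 861 changed at least 2-fold.

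CLA18:3 against DMSO asks what the acid with 3 conjugated double bonds changed at 5 µM. FOS rose by 6.06 ± 0.22, adjusted p = 4.1e-21, GCNT3 by 6.0 ± 0.28, HMOX1 by 5.16 ± 0.12, adjusted p = 1.1e-26 and CXCL8 by 3.65 ± 0.16. HMOX1 lay at 868 to 1026 CPM against 24.4 to 29.8 in DMSO. CHAC1, a glutathione-degrading enzyme, rose by 1.89 ± 0.15, DDIT3 by 1.92 ± 0.15, ATF3 by 1.78 ± 0.08 and GPX4 by 0.37 ± 0.07, adjusted p = 8.7e-05. CPT1A rose by 0.41 ± 0.09, while the sterol gene INSIG1, at -0.04 (95% interval -0.13 to 0.05), did not pass. The collagen gene COL1A1 fell by 1.46 ± 0.09. 28 of 29 NRF2 targets rose and 0 fell (28 and 0 adjusted over the list alone, adjusted p = 2.6e-100), with SLC7A11 at 2.81 ± 0.09 and OSGIN1 at 3.25 ± 0.08. Among 45 cytosolic ribosomal protein genes, 44 rose and 0 fell (44 and 0 adjusted over the list alone, adjusted p = 7.4e-17), with RPL11 at 0.53 ± 0.05. For nuclear-encoded respiratory chain genes, 35 of 43 rose and 0 fell (38 and 0 adjusted over the list alone, adjusted p = 2.5e-10), with COX6C at 0.62 ± 0.07. Of the 29 ATF4 and integrated stress response genes, 21 rose and 0 fell (26 and 1 adjusted over the list alone, adjusted p = 2.2e-31), with PPP1R15A at 1.63 ± 0.05. 20 of 21 ER unfolded protein response genes rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p = 1.9e-31), with HSPA5 at 1.28 ± 0.03 and DNAJB9 at 1.88 ± 0.10. Among 17 cytosolic heat shock genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, adjusted p = 2.5e-10), with HSPA8 at 0.58 ± 0.04. For NF-kappaB and cytokine genes, 11 of 17 rose and 1 fell (12 and 2 adjusted over the list alone, adjusted p = 4.9e-07), with NFKBIA, the inhibitor of NF-kappaB, at 1.0 ± 0.08. Of the 23 immediate early and AP-1 genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 7.4e-06), with FOSB at 2.52 ± 0.16 and EGR1 at 1.81 ± 0.14. Lists called besides these include p53 targets (13 and 3 of 26 higher and lower, 14 and 4 adjusted over the list alone, adjusted p = 0.00676, up), type I interferon response genes (7 and 0 of 21 higher and lower, 7 and 0 adjusted over the list alone, adjusted p = 0.0150, up) and lysosome and autophagy genes (19 and 2 of 29 higher and lower, 21 and 2 adjusted over the list alone, adjusted p = 4.7e-20, up). Of 28 lists, 18 passed, 16 higher and 2 lower, 16 of them also with an estimated correlation. These gene groups come from libraries with fewer detected genes (19378 ± 801) and the widest replicate spread (20.0%). CLA18:3 changed 5856 genes, 3125 higher and 2731 lower, 619 at least 2-fold.

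**Figure D3:**
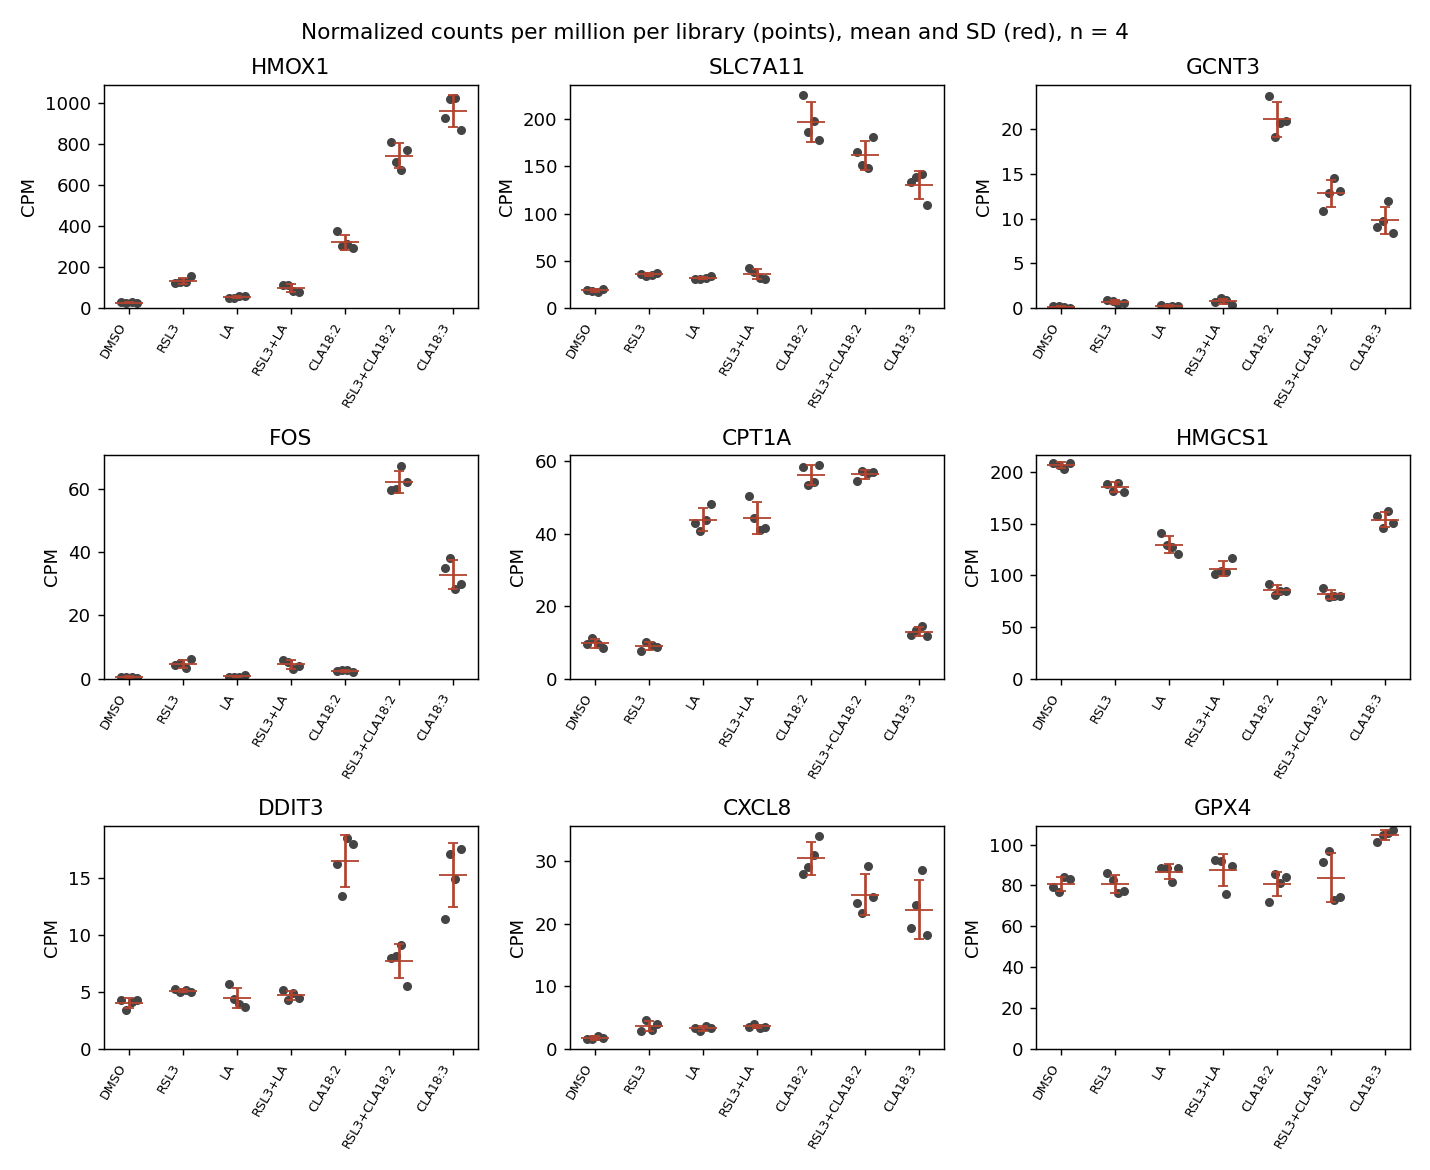
CPM of 9 genes in each library (points) of the 7 groups, with the group mean and SD in red (n = 4). HMOX1 averages 960.2 CPM with CLA18:3 and 26.9 in DMSO, and CPT1A 43.9 with LA and 9.69 in DMSO.

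CLA18:2 against LA compares the isomers at a matched 80 µM. Conjugation went with higher GCNT3 (6.61 ± 0.25, adjusted p = 1.2e-20), CXCL8 (3.20 ± 0.15), OSGIN1 (3.02 ± 0.08), SLC7A11 (2.63 ± 0.09, adjusted p = 5.6e-22) and HMOX1 (2.58 ± 0.10, adjusted p = 5.7e-20). DDIT3 was higher by 1.90 ± 0.15, AIFM2 by 1.59 ± 0.08, PTGS2, the inducible cyclooxygenase, by 1.01 ± 0.15 and ALDH2, a mitochondrial aldehyde dehydrogenase, by 1.94 ± 0.09. SCD (-1.01 ± 0.05, adjusted p = 1.1e-18), INSIG1 (-0.87 ± 0.05) and THBS1 (-1.38 ± 0.07) were lower with CLA18:2. CPT1A, up with both acids, was higher with CLA18:2 by 0.36 ± 0.08, adjusted p = 4.9e-04. No difference was detected for GPX4, -0.11 (95% interval -0.25 to 0.04), ACSL4, which activates polyunsaturated acids, -0.06 (95% interval -0.16 to 0.05), or TFRC, the transferrin receptor, -0.05 (95% interval -0.14 to 0.04). ANGPTL4, 0.54 (95% interval -0.20 to 1.28), did not pass either and has a wide interval at low counts. The metallothionein gene MT2A, 0.13 (95% interval 0.01 to 0.25), did not pass after adjustment, though its unadjusted interval lies above 0. 28 of 29 NRF2 targets were higher and 0 were lower (28 and 0 adjusted over the list alone, adjusted p = 1.9e-76). Among 21 ER unfolded protein response genes, 20 were higher and 0 were lower (20 and 0 adjusted over the list alone, adjusted p = 2.3e-19), with HSPA5 at 0.99 ± 0.03. For cholesterol synthesis and SREBP2 target genes, 0 of 24 were higher and 19 were lower (0 and 20 adjusted over the list alone, adjusted p = 8.3e-15), with HMGCS1 at -0.59 ± 0.05 and SQLE at -0.63 ± 0.06. Of the 25 mitotic and proliferation genes, 0 were higher and 24 were lower (0 and 24 adjusted over the list alone, adjusted p = 9.3e-16), with UBE2C at -0.60 ± 0.05. For DNA replication genes, 0 of 31 were higher and 26 were lower (0 and 27 adjusted over the list alone, adjusted p = 5.5e-21), with MCM2 at -0.56 ± 0.04. Among 29 lysosome and autophagy genes, 22 were higher and 1 was lower (24 and 1 adjusted over the list alone, adjusted p = 2.1e-22), with CTSD at 1.28 ± 0.05. For ferroptosis regulators, 20 of 41 were higher and 6 were lower (20 and 6 adjusted over the list alone, adjusted p = 6.7e-11). Among further lists past the test were ATF4 and integrated stress response genes (20 and 2 of 29 higher and lower, 21 and 2 adjusted over the list alone, adjusted p = 1.6e-13, up) and aldehyde and electrophile detoxification genes (11 and 2 of 19 higher and lower, 12 and 2 adjusted over the list alone, adjusted p = 2.4e-07, up). In all 16 of 28 lists passed (12 higher, 4 lower), and 13 held with an estimated correlation. CLA18:2 had fewer detected genes and a lower mean mitochondrial share than LA (values above). The PPAR list (10 higher and 2 lower of 30, 10 and 2 adjusted over the list alone, adjusted p = 0.211) did not pass. In all 4929 genes differed, 2551 higher and 2378 lower with CLA18:2, 450 at least 2-fold.

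CLA18:2 was given at 80 µM and CLA18:3 at 5 µM, so their values stand side by side without a test between them. Against DMSO, with CLA18:2 first and CLA18:3 second, the changes were HMOX1 3.57 ± 0.11 and 5.16 ± 0.12, SLC7A11 3.40 ± 0.09 and 2.81 ± 0.09, GCLM 1.69 ± 0.07 and 1.69 ± 0.07 and OSGIN1 3.26 ± 0.08 and 3.25 ± 0.08. The ER stress genes gave HSPA5 1.33 ± 0.03 and 1.28 ± 0.03 and DDIT3 2.03 ± 0.15 and 1.92 ± 0.15. Sterol and lipid genes gave HMGCS1 -1.27 ± 0.05 and -0.43 ± 0.05, SCD -1.59 ± 0.05 and -0.26 ± 0.04 and CPT1A 2.53 ± 0.09 and 0.41 ± 0.09. Across 16325 genes, which are not independent replicates, the changes had r = 0.609, with 0.289 simulated for unchanged groups against the same DMSO libraries and 0.491 against separate DMSO libraries. Of the genes called in both, 1871 were higher with both, where independent lists would share 629. Another 1465 were lower with both against 509, and 233 went opposite ways. With separate DMSO libraries, fewer per response, 1385 higher and 972 lower were shared.

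**Figure D4:**
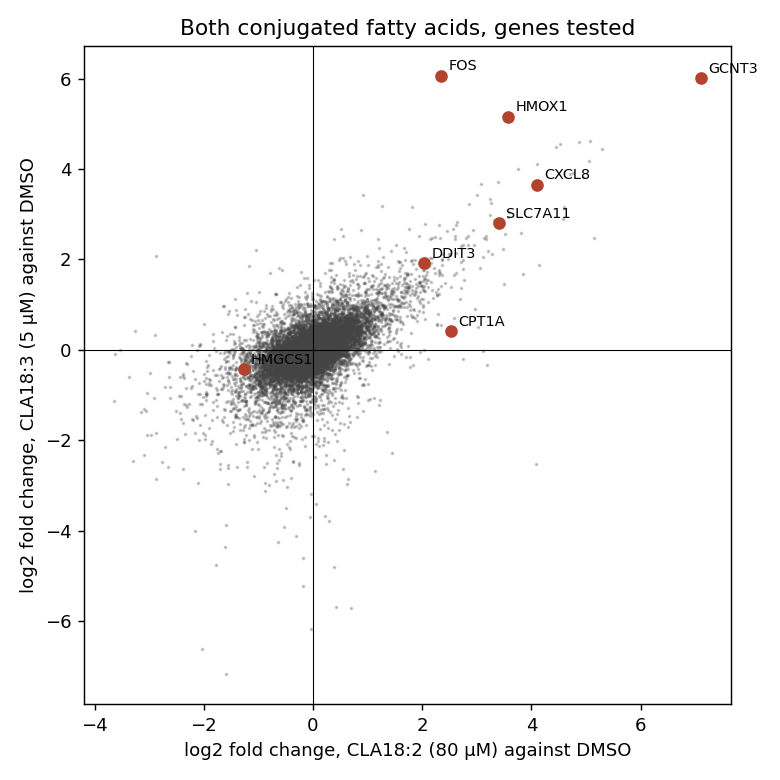
Each point is a gene, with its log2 fold change against DMSO with 80 µM CLA18:2 on the horizontal axis and with 5 µM CLA18:3 on the vertical axis. The correlation across 16325 genes is 0.609, and simulated unchanged groups that share the DMSO libraries give 0.289.

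RSL3+LA against DMSO shows the combined treatment. CPT1A rose by 2.19 ± 0.09, adjusted p = 6.0e-19 and FOS by 3.18 ± 0.27, adjusted p = 7.2e-11, to 2.97 to 5.82 CPM from 0.167 to 0.631. HMOX1 rose by 1.84 ± 0.11, adjusted p = 1.4e-14, SLC7A11 by 0.94 ± 0.10, FTH1 by 0.60 ± 0.08 and CXCL8 by 1.03 ± 0.18. HMGCS1 (-0.96 ± 0.05, adjusted p = 8.3e-16), SCD (-0.78 ± 0.04) and ACSL4 (-0.32 ± 0.05) fell, and TGFB2 fell by 1.37 ± 0.11. GPX4 was at 0.11 (95% interval -0.03 to 0.26). Of the 24 cholesterol synthesis and SREBP2 target genes, 0 rose and 19 fell (1 and 21 adjusted over the list alone, adjusted p = 1.6e-43), with ACAT2 at -0.78 ± 0.06. 21 of 29 NRF2 targets rose and 0 fell (26 and 0 adjusted over the list alone, adjusted p = 5.0e-35), with NQO1 at 0.58 ± 0.06 and GCLM at 0.49 ± 0.07. Among 30 PPAR targets and fatty acid oxidation genes, 9 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 9.3e-15), with ACAA2 at 1.03 ± 0.06. For hypoxia and HIF1 targets, 12 of 26 rose and 2 fell (15 and 2 adjusted over the list alone, adjusted p = 3.9e-06), with PFKFB4, a regulator of glycolysis, at 0.77 ± 0.10. The test also called fatty acid synthesis and desaturation genes (2 and 5 of 22 higher and lower, 2 and 6 adjusted over the list alone, adjusted p = 0.00124, down), ER unfolded protein response genes (8 and 0 of 21 higher and lower, 10 and 0 adjusted over the list alone, adjusted p = 1.7e-06, up) and lysosome and autophagy genes (5 and 1 of 29 higher and lower, 8 and 1 adjusted over the list alone, adjusted p = 8.6e-06, up). The lists past the test numbered 16 of 28, 11 higher and 5 lower, with 10 left under an estimated correlation. Libraries of RSL3+LA held 1.65 ± 0.202% mitochondrial mRNA and 21845 ± 685 detected genes, those of DMSO 1.40 ± 0.101% and 22745 ± 109. The count was 1672 genes, 887 higher and 785 lower, 97 at least 2-fold, and 2608 with limma voom.

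RSL3+LA against RSL3 shows what LA added to the inhibitor. CPT1A (2.30 ± 0.09, adjusted p = 4.4e-19), SLC25A20 (1.19 ± 0.12) and ACAA2 (1.04 ± 0.06) were higher with LA. HMGCS1 (-0.80 ± 0.05, adjusted p = 1.4e-13), SCD (-0.70 ± 0.04) and ACSL4 (-0.39 ± 0.05) were lower. HMOX1 (-0.46 ± 0.10, adjusted p = 0.00196), ATF3 (-0.87 ± 0.09, adjusted p = 2.6e-09) and CHAC1 (-0.68 ± 0.16) were also lower. SLC7A11 did not differ detectably, at 0.00 (95% interval -0.18 to 0.19). Of the 24 cholesterol synthesis and SREBP2 target genes, 0 were higher and 19 were lower (0 and 22 adjusted over the list alone, adjusted p = 6.1e-44), with DHCR7 at -0.58 ± 0.05. 9 of 30 PPAR targets and fatty acid oxidation genes were higher and 1 was lower (9 and 1 adjusted over the list alone, adjusted p = 4.2e-16), with ECH1 at 0.88 ± 0.08. Among 23 immediate early and AP-1 genes, 0 were higher and 6 were lower (0 and 7 adjusted over the list alone, adjusted p = 6.0e-05), with KLF6 at -0.34 ± 0.04. For DNA replication genes, 0 of 31 were higher and 9 were lower (0 and 14 adjusted over the list alone, adjusted p = 4.5e-08), with CDC6 at -0.40 ± 0.04. Of the 29 NRF2 targets, 9 were higher and 1 was lower (10 and 2 adjusted over the list alone, adjusted p = 6.0e-05), with FTL at 0.41 ± 0.05 and the transporter ABCC3 at 1.06 ± 0.15. Past the test, too, were fatty acid synthesis and desaturation genes (1 and 6 of 22 higher and lower, 1 and 9 adjusted over the list alone, adjusted p = 6.0e-05, down) and metallothioneins (2 and 0 of 4 higher and lower, 2 and 0 adjusted over the list alone, adjusted p = 0.00481, up). Of 28 lists, 17 passed, 9 higher and 8 lower, 7 of them also with an estimated correlation. RSL3+LA had a higher mean mitochondrial share and fewer detected genes than RSL3 (values above). In total 1564 genes differed, 617 higher and 947 lower, 61 at least 2-fold.

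RSL3+LA against LA shows what RSL3 added to LA. FOS was higher by 2.69 ± 0.25, adjusted p = 2.8e-08, to 2.97 to 5.82 CPM from 0.476 to 1.06, FOSB by 1.43 ± 0.17, adjusted p = 7.5e-06 and HMOX1 by 0.85 ± 0.10, adjusted p = 7.5e-06. The other higher genes were ATF3 (0.47 ± 0.09, adjusted p = 0.0242, adjusted p 0.126 to 0.168 without each of RSL3+LA replicates 1 and 2 and LA replicates 3 and 4), GCNT3 (1.78 ± 0.36, adjusted p = 0.0434, adjusted p 0.0563 to 0.252 without each of RSL3+LA replicates 1, 2 and 3 and LA replicates 1, 2, 3 and 4) and NPIPB5 (0.74 ± 0.12, adjusted p = 0.00374, adjusted p 0.0713 without RSL3+LA replicate 3), the last a member of a repeated family whose reads can map to several copies. GCNT3 had adjusted p = 0.0618 with a replicate block. Among the lower genes was HMGCS1 (-0.28 ± 0.05, adjusted p = 0.00906, adjusted p 0.0803 to 0.158 without each of RSL3+LA replicates 1, 2 and 3 and LA replicate 1). 1 of 29 NRF2 targets were higher and 0 were lower (5 and 0 adjusted over the list alone, adjusted p = 5.1e-12), with a median of 0.12. Among 24 cholesterol synthesis and SREBP2 target genes, 0 were higher and 2 were lower (1 and 11 adjusted over the list alone, adjusted p = 2.4e-10), with a median of -0.14. For immediate early and AP-1 genes, 3 of 23 were higher and 0 were lower (4 and 1 adjusted over the list alone, adjusted p = 1.3e-05). Of the 26 p53 targets, 0 were higher and 0 were lower (0 and 0 adjusted over the list alone, adjusted p = 0.00331), with a median of -0.07. In all 8 of 28 lists passed (4 higher, 4 lower), and 4 held with an estimated correlation. RSL3+LA had fewer detected genes and a higher mean mitochondrial share than LA (values above). As a list, mitochondrially encoded mRNAs were higher (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 4.9e-06, adjusted p = 0.383 with an estimated correlation). The count was 8 genes, 6 higher and 2 lower, 3 at least 2-fold, with 1158 past the unadjusted threshold. DESeq2 called 37 (14 higher, 23 lower), 26 (16 higher, 10 lower) without independent filtering, and limma voom 32 (15 higher, 17 lower). It was 164 with no low-count filter, 4 without each of RSL3+LA replicates 1, 2 and 3, and 5 without each of LA replicates 3 and 4.

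The interaction of RSL3 with LA tests whether the response to RSL3 differed in the presence of LA. The response of HMOX1 was smaller with LA, with a difference of -1.45 ± 0.15, adjusted p = 4.3e-07, that is 2.30 ± 0.11 without LA and 0.85 ± 0.10 with it. DDIT4 also responded less (-1.61 ± 0.24, adjusted p = 7.0e-04). The same held for SLC7A11 (-0.76 ± 0.13, adjusted p = 0.00913, adjusted p 0.0708 without DMSO replicate 3) and for NPC1, a lysosomal cholesterol transporter (-0.39 ± 0.07, adjusted p = 0.00677). For ATF4 and integrated stress response genes, 0 of 29 were higher in the interaction and 1 lower (0 and 5 adjusted over the list alone, adjusted p = 1.2e-08). Among 29 NRF2 targets, 0 were higher and 2 lower (0 and 4 adjusted over the list alone, adjusted p = 1.4e-08). For ferroptosis regulators, 0 of 41 were higher and 2 lower (0 and 4 adjusted over the list alone, adjusted p = 1.5e-07), HMOX1 and SLC7A11 as in the NRF2 list. Of the 24 cholesterol synthesis and SREBP2 target genes, 0 were higher and 0 lower (0 and 4 adjusted over the list alone, adjusted p = 5.1e-05). Among further lists past the test were cytosolic heat shock genes (0 and 0 of 17 higher and lower, 0 and 6 adjusted over the list alone, adjusted p = 7.2e-06, down) and ER unfolded protein response genes (0 and 0 of 21 higher and lower, 0 and 1 adjusted over the list alone, adjusted p = 7.2e-05, down). The lists past the test numbered 10 of 28, 1 higher and 9 lower, with 6 left under an estimated correlation. As a list, mitochondrially encoded mRNAs were higher (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 1.8e-06, adjusted p = 0.327 with an estimated correlation). edgeR called 4 genes, 0 higher and 4 lower, and 985 passed without adjustment. DESeq2 called 37 (1 higher, 36 lower), but its independent filtering left out 15508 of 16325 genes, and without it the count was 6 (1 higher, 5 lower). limma voom called 25 (5 higher, 20 lower), and with no low-count filter edgeR called 132. Without the libraries under 0.8% mitochondrial mRNA it called 2, HMOX1 and DDIT4.

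RSL3+CLA18:2 against DMSO shows the other combination. FOS rose by 6.98 ± 0.22, adjusted p = 3.5e-23, GCNT3 by 6.39 ± 0.27, HMOX1 by 4.78 ± 0.12, adjusted p = 4.0e-26 and FOSB by 3.85 ± 0.16. HMOX1 lay at 672 to 811 CPM against 24.4 to 29.8. CXCL8 (3.80 ± 0.16), SLC7A11 (3.11 ± 0.09), EGR1 (3.31 ± 0.14), CPT1A (2.54 ± 0.09) and ATF3 (1.82 ± 0.08) rose. TGFB2 (-2.82 ± 0.12, adjusted p = 3.2e-19), SCD (-1.52 ± 0.05), HMGCS1 (-1.34 ± 0.05) and the kinase gene NUAK2 (-2.45 ± 0.21) fell. GPX4 was at 0.05 (95% interval -0.10 to 0.20). 28 of 29 NRF2 targets rose and 0 fell (29 and 0 adjusted over the list alone, adjusted p = 1.1e-92), with GCLM at 1.96 ± 0.07. Among 24 cholesterol synthesis and SREBP2 target genes, 0 rose and 21 fell (0 and 21 adjusted over the list alone, adjusted p = 9.2e-31), with INSIG1 at -1.06 ± 0.05. For ER unfolded protein response genes, 20 of 21 rose and 0 fell (20 and 0 adjusted over the list alone, adjusted p = 2.3e-18), with HSPA5 at 0.89 ± 0.03. Of the 23 immediate early and AP-1 genes, 12 rose and 4 fell (14 and 4 adjusted over the list alone, adjusted p = 1.7e-10). 22 of 29 lysosome and autophagy genes rose and 2 fell (23 and 2 adjusted over the list alone, adjusted p = 1.9e-17), with SQSTM1 at 2.31 ± 0.05. Among 17 NF-kappaB and cytokine genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 2.5e-05), with NFKBIA at 1.16 ± 0.08. The test also called ATF4 and integrated stress response genes (18 and 2 of 29 higher and lower, 19 and 2 adjusted over the list alone, adjusted p = 1.5e-11, up), ferroptosis regulators (19 and 6 of 41 higher and lower, 19 and 9 adjusted over the list alone, adjusted p = 2.6e-10, up) and aldehyde and electrophile detoxification genes (12 and 3 of 19 higher and lower, 13 and 3 adjusted over the list alone, adjusted p = 1.3e-07, up). Of 28 lists, 20 passed, 14 higher and 6 lower, 12 of them also with an estimated correlation. As a list, mitochondrially encoded mRNAs were lower (0 higher and 4 lower of 13, 0 and 10 adjusted over the list alone, adjusted p = 0.00643, adjusted p = 0.483 with an estimated correlation). These libraries had a mitochondrial mRNA share of 0.640 ± 0.692% and 20015 ± 1119.6 detected genes. The count was 5752 genes, 3042 higher and 2710 lower, 801 at least 2-fold.

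RSL3+CLA18:2 against RSL3 shows what CLA18:2 added to the inhibitor. GCNT3 (4.30 ± 0.22, adjusted p = 2.9e-17), FOS (3.75 ± 0.16, adjusted p = 3.7e-19), CXCL8 (2.74 ± 0.15), HMOX1 (2.48 ± 0.10, adjusted p = 1.1e-19), OSGIN1 (2.43 ± 0.08) and SLC7A11 (2.18 ± 0.09) were higher. CPT1A was higher by 2.65 ± 0.09, AIFM2 by 1.45 ± 0.08 and DDIT3 by 0.59 ± 0.16. TGFB2 (-2.57 ± 0.12), SCD (-1.44 ± 0.05, adjusted p = 1.7e-22) and HMGCS1 (-1.18 ± 0.05) were lower. For NRF2 targets, 29 of 29 were higher and 0 were lower (29 and 0 adjusted over the list alone, adjusted p = 5.4e-76). Of the 24 cholesterol synthesis and SREBP2 target genes, 0 were higher and 22 were lower (0 and 22 adjusted over the list alone, adjusted p = 2.3e-36), with MSMO1 at -1.13 ± 0.07. 19 of 21 ER unfolded protein response genes were higher and 0 were lower (20 and 0 adjusted over the list alone, adjusted p = 2.9e-16), with HSPA5 at 0.72 ± 0.03. Among 29 lysosome and autophagy genes, 20 were higher and 2 were lower (21 and 2 adjusted over the list alone, adjusted p = 7.5e-16), with GLA, a lysosomal galactosidase, at 1.47 ± 0.06. For PPAR targets and fatty acid oxidation genes, 17 of 30 were higher and 2 were lower (17 and 2 adjusted over the list alone, adjusted p = 1.1e-08), with SLC25A20 at 1.45 ± 0.12. Past the test, too, were aldehyde and electrophile detoxification genes (12 and 2 of 19 higher and lower, 12 and 2 adjusted over the list alone, adjusted p = 3.7e-07, up) and immediate early and AP-1 genes (11 and 3 of 23 higher and lower, 11 and 3 adjusted over the list alone, adjusted p = 5.1e-07, up). In all 20 of 28 lists passed (14 higher, 6 lower), and 13 held with an estimated correlation. RSL3+CLA18:2 had a lower mean mitochondrial share and fewer detected genes than RSL3 (values above). Mitochondrially encoded mRNAs were as a list lower (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 0.0126, adjusted p = 0.535 with an estimated correlation). The difference covered 4967 genes, 2593 higher and 2374 lower, 607 at least 2-fold.

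RSL3+CLA18:2 against CLA18:2 shows what RSL3 added to the conjugated acid. FOS was higher by 4.64 ± 0.18, adjusted p = 1.2e-19, to 59.7 to 67.4 CPM from 2.14 to 2.74, FOSB by 3.30 ± 0.15, adjusted p = 1.9e-17, ATF3 by 1.49 ± 0.08, adjusted p = 4.5e-15, HMOX1 by 1.21 ± 0.10, adjusted p = 1.8e-10, EGR1 by 1.09 ± 0.12 and E2F2, an S-phase factor, by 1.09 ± 0.18. DDIT3 (-1.10 ± 0.15, adjusted p = 2.8e-06), HSPA5 (-0.44 ± 0.03, adjusted p = 8.8e-11), SESN2 (-0.55 ± 0.06), SQSTM1 (-0.44 ± 0.05) and the p53 regulator MDM2 (-0.37 ± 0.05) were lower. Of the 25 mitotic and proliferation genes, 24 were higher and 0 were lower (24 and 0 adjusted over the list alone, adjusted p = 4.3e-42), with BIRC5 at 0.46 ± 0.04, CDK1 at 0.44 ± 0.06 and CCNB1 at 0.33 ± 0.04. 29 of 31 DNA replication genes were higher and 0 were lower (31 and 0 adjusted over the list alone, adjusted p = 8.5e-53), with RRM2 at 0.51 ± 0.04, CDC6 at 0.49 ± 0.04 and FEN1 at 0.42 ± 0.04. Among 21 ER unfolded protein response genes, 0 were higher and 9 were lower (0 and 10 adjusted over the list alone, adjusted p = 1.2e-05), with HYOU1 at -0.34 ± 0.04. For ATF4 and integrated stress response genes, 3 of 29 were higher and 13 were lower (4 and 13 adjusted over the list alone, adjusted p = 0.00140), with GDF15 at -0.41 ± 0.06. Of the 26 p53 targets, 3 were higher and 8 were lower (3 and 9 adjusted over the list alone, adjusted p = 1.9e-04), with CDKN1A, the p21 gene, at -0.33 ± 0.04. 9 of 23 immediate early and AP-1 genes were higher and 1 was lower (10 and 4 adjusted over the list alone, adjusted p = 3.9e-17). Among 29 lysosome and autophagy genes, 0 were higher and 7 were lower (0 and 11 adjusted over the list alone, adjusted p = 2.5e-05). The lists past the test numbered 8 of 28, 4 higher and 4 lower, with 7 left under an estimated correlation. RSL3+CLA18:2 had fewer detected genes and a lower mean mitochondrial share than CLA18:2 (values above). The count was 1942 genes, 1086 higher and 856 lower, 92 at least 2-fold, and 849 without the libraries under 0.8% mitochondrial mRNA, which left 1 library against 2.

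The interaction of RSL3 with CLA18:2 tests whether the response to RSL3 differed with the conjugated acid. RSL3 raised HMOX1 by 2.30 ± 0.11 without CLA18:2 and by 1.21 ± 0.10 with it, a difference of -1.09 ± 0.14, adjusted p = 1.3e-05. SLC7A11 (-1.22 ± 0.13, adjusted p = 9.8e-08), DDIT3 (-1.44 ± 0.22), DDIT4 (-2.26 ± 0.23, adjusted p = 5.6e-08), GCNT3 (-2.82 ± 0.43, rough at low counts), HSPA5 (-0.61 ± 0.05, adjusted p = 6.5e-10) and SQSTM1 (-0.87 ± 0.07) were also lower in the interaction. For some this was a fall: RSL3 changed SLC7A11 by 0.93 ± 0.10 without CLA18:2 and -0.29 ± 0.08 with it, and DDIT3 by 0.34 ± 0.16 and -1.10 ± 0.15. FOSB (2.06 ± 0.22, adjusted p = 2.5e-07) and ATF3 (0.65 ± 0.12) had a higher response. For DNA replication genes, 21 of 31 were higher in the interaction and 0 lower (29 and 0 adjusted over the list alone, adjusted p = 4.2e-35), with RRM2 at 0.42 ± 0.06. Of the 25 mitotic and proliferation genes, 16 were higher and 0 lower (22 and 0 adjusted over the list alone, adjusted p = 1.2e-27), with BIRC5 at 0.41 ± 0.06 and CCNA2 at 0.38 ± 0.07. For NRF2 targets, 0 of 29 were higher and 12 lower (0 and 15 adjusted over the list alone, adjusted p = 3.5e-19), with FTL at -0.65 ± 0.06. Among 29 ATF4 and integrated stress response genes, 1 was higher and 12 lower (1 and 13 adjusted over the list alone, adjusted p = 6.5e-16), with SESN2 at -0.81 ± 0.09. For ER unfolded protein response genes, 0 of 21 were higher and 10 lower (0 and 10 adjusted over the list alone, adjusted p = 1.1e-11), with HYOU1 at -0.41 ± 0.06. Among further lists past the test were lysosome and autophagy genes (0 and 6 of 29 higher and lower, 0 and 11 adjusted over the list alone, adjusted p = 9.3e-11, down) and ferroptosis regulators (0 and 9 of 41 higher and lower, 0 and 10 adjusted over the list alone, adjusted p = 1.5e-06, down). Of 28 lists, 15 passed, 6 higher and 9 lower, 9 of them also with an estimated correlation. The p53 list had adjusted p = 0.0562 with a replicate block. There were 580 genes, 286 higher and 294 lower, and 2496 unadjusted. The count was 889 with DESeq2, 1029 with limma voom and 198 without the libraries under 0.8% mitochondrial mRNA.

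RSL3+CLA18:2 against RSL3+LA compares the isomers at 80 µM with the inhibitor present. GCNT3 (4.11 ± 0.21, adjusted p = 8.3e-17), FOS (3.80 ± 0.16, adjusted p = 3.7e-19), EGR1 (3.03 ± 0.14), HMOX1 (2.94 ± 0.10, adjusted p = 4.2e-21), CXCL8 (2.77 ± 0.14) and SLC7A11 (2.18 ± 0.09) were higher with the conjugated isomer. AIFM2 was higher by 1.37 ± 0.08 and ATF3 by 1.85 ± 0.08. SCD (-0.74 ± 0.05, adjusted p = 6.7e-15), INSIG1 (-0.53 ± 0.05) and HMGCS1 (-0.38 ± 0.05) were lower. No difference was detected for GPX4, -0.06 (95% interval -0.21 to 0.08), TFRC, 0.07 (95% interval -0.02 to 0.16), FADS1, the delta-5 desaturase, -0.01 (95% interval -0.10 to 0.08), or MT2A, 0.06 (95% interval -0.06 to 0.17). Of the 29 NRF2 targets, 27 were higher and 0 were lower (28 and 0 adjusted over the list alone, adjusted p = 3.7e-75). 13 of 23 immediate early and AP-1 genes were higher and 2 were lower (15 and 2 adjusted over the list alone, adjusted p = 2.1e-17), with FOSB at 2.74 ± 0.14. Among 29 lysosome and autophagy genes, 14 were higher and 1 was lower (15 and 1 adjusted over the list alone, adjusted p = 1.1e-14), with GABARAPL1 at 1.48 ± 0.07. For ER unfolded protein response genes, 20 of 21 were higher and 0 were lower (20 and 0 adjusted over the list alone, adjusted p = 1.1e-14), with HERPUD1 at 0.71 ± 0.06. Of the 41 ferroptosis regulators, 19 were higher and 5 were lower (21 and 5 adjusted over the list alone, adjusted p = 3.8e-12). For cholesterol synthesis and SREBP2 target genes, 0 of 24 were higher and 16 were lower (0 and 17 adjusted over the list alone, adjusted p = 9.9e-08), with MSMO1 at -0.57 ± 0.07. The test also called ATF4 and integrated stress response genes (17 and 2 of 29 higher and lower, 18 and 2 adjusted over the list alone, adjusted p = 3.4e-09, up) and cytosolic heat shock genes (11 and 2 of 17 higher and lower, 12 and 2 adjusted over the list alone, adjusted p = 7.0e-06, up). In all 13 of 28 lists passed (10 higher, 3 lower), and 11 held with an estimated correlation. RSL3+CLA18:2 had fewer detected genes and a lower mean mitochondrial share than RSL3+LA (values above). Mitochondrially encoded mRNAs were as a list lower (0 higher and 9 lower of 13, 0 and 13 adjusted over the list alone, adjusted p = 1.1e-04, adjusted p = 0.371 with an estimated correlation). Mitotic and proliferation genes (0 higher and 4 lower of 25, 0 and 4 adjusted over the list alone, adjusted p = 0.354) and DNA replication genes (4 higher and 10 lower of 31, 4 and 11 adjusted over the list alone, adjusted p = 0.122) did not pass. In this comparison 4254 genes differed, 2296 higher and 1958 lower, 493 at least 2-fold.

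The interaction of RSL3 with the isomer tests whether the response to RSL3 differed between CLA18:2 and LA. ATF3 (1.02 ± 0.12, adjusted p = 5.3e-06) and FOSB (1.87 ± 0.23, adjusted p = 8.2e-06) responded more with CLA18:2. GCNT3 (-2.50 ± 0.39, rough at low counts), HSPA5 (-0.41 ± 0.05, adjusted p = 5.3e-06), OSGIN1 (-0.56 ± 0.11), SQSTM1 (-0.62 ± 0.07) and FTL (-0.50 ± 0.06) were lower in this test. Lower can mean a fall with RSL3 and not a smaller rise. With RSL3, HSPA5 fell by 0.44 ± 0.03 in CLA18:2, while its -0.03 ± 0.03 in LA did not pass (adjusted p = 0.933). OSGIN1 had -0.15 ± 0.07 in CLA18:2 and 0.41 ± 0.09 in LA. Neither value passed on its own (adjusted p = 0.184 and 0.0717), so no fall of OSGIN1 is shown. INSIG1 (0.34 ± 0.07) and THBS1 (0.61 ± 0.10) were higher in this test. HMOX1 did not pass after adjustment, at 0.36 (95% interval 0.07 to 0.64), an unadjusted interval above 0, nor did GPX4, at 0.04 (95% interval -0.16 to 0.25), or CPT1A, at -0.01 (95% interval -0.24 to 0.21). Among 31 DNA replication genes, 21 were higher in the interaction and 0 lower (29 and 0 adjusted over the list alone, adjusted p = 3.9e-40), with CDC6 at 0.47 ± 0.06 and FEN1 at 0.40 ± 0.05. For mitotic and proliferation genes, 23 of 25 were higher in the interaction and 0 lower (24 and 0 adjusted over the list alone, adjusted p = 5.7e-33), with CDK1 at 0.45 ± 0.08 and CCNB1 at 0.34 ± 0.06. Of the 24 cholesterol synthesis and SREBP2 target genes, 4 were higher in the interaction and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 1.2e-06). For lysosome and autophagy genes, 0 of 29 were higher in the interaction and 5 lower (0 and 5 adjusted over the list alone, adjusted p = 1.1e-06). Past the test, too, were NRF2 targets (0 and 4 of 29 higher and lower, 2 and 9 adjusted over the list alone, adjusted p = 1.3e-05, down) and immediate early and AP-1 genes (5 and 0 of 23 higher and lower, 7 and 0 adjusted over the list alone, adjusted p = 1.9e-05, up). The lists past the test numbered 14 of 28, 7 higher and 7 lower, with 9 left under an estimated correlation. Mitochondrially encoded mRNAs were as a list lower (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 9.1e-05, adjusted p = 0.387 with an estimated correlation). It covered 593 genes, 394 higher and 199 lower, with 2554 unadjusted. The count was 203 without the libraries under 0.8% mitochondrial mRNA, 374 without RSL3+LA replicate 1, 379 without LA replicate 3 and 377 without CLA18:2 replicate 2.

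**Figure D5:**
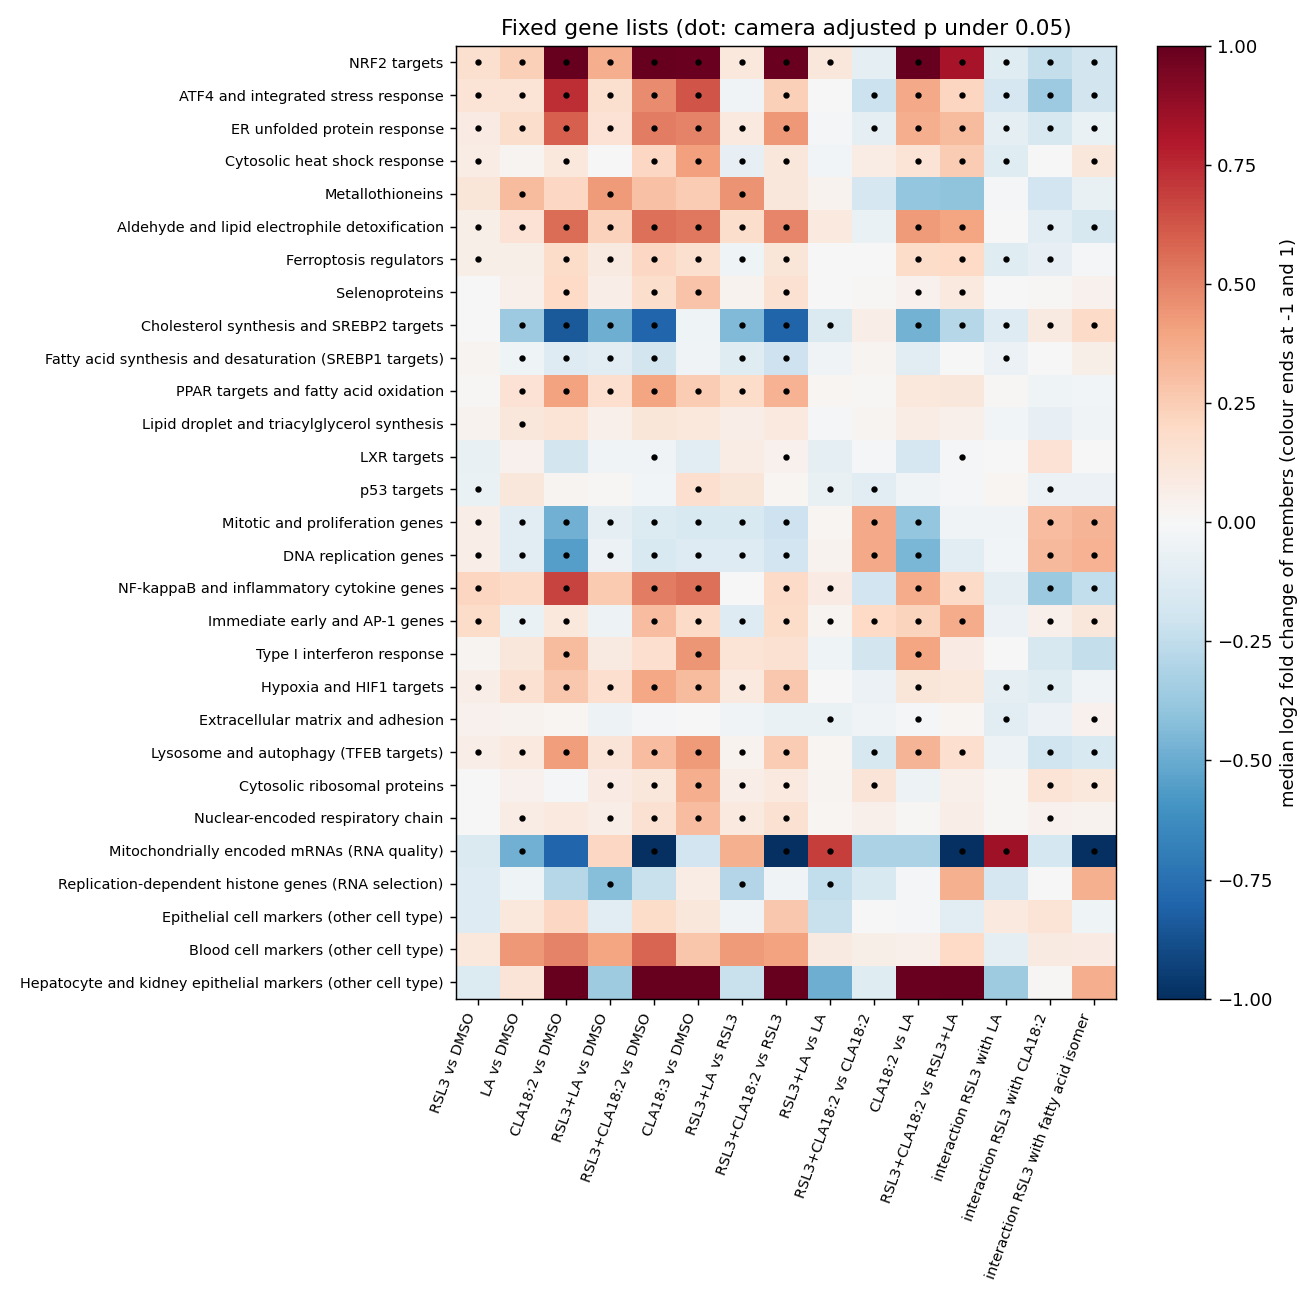
Colors give the median log2 fold change of each fixed list (vertical axis) in each comparison (horizontal axis), and dots mark a camera adjusted p under 0.05. NRF2 targets have a median of 1.26 with CLA18:2, 0.23 with LA and 0.16 with RSL3.

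Responses were also compared across 16325 genes, which are not independent replicates, for 15 pairs sharing the DMSO libraries. Unchanged groups sharing DMSO gave simulated r from 0.232 to 0.457, and 3 pairs lay below theirs. Such groups hold only noise, so their r is not the part of an observed r due to sharing. Covariance exceeded the simulated in every pair. CLA18:2 with and without RSL3 had r = 0.766, simulated 0.316, and 0.638 against separate DMSO libraries. Their covariance was 0.286 against 0.0272 simulated, with 2428 genes higher in both where independent lists share 612, and 1948 lower in both against 505, or 1825 higher and 1326 lower with separate DMSO libraries. LA with and without RSL3 had r = 0.601, simulated 0.423 and 0.293 against separate DMSO libraries, with covariance 0.0737 against 0.0263. They shared 568 higher genes against 43.5 and 421 lower against 26.8, or 286 higher and 224 lower with separate ones. LA and CLA18:2 had r = 0.542, simulated 0.427 and 0.349 likewise, with covariance 0.111 against 0.0262. They shared 643 higher genes against 161 and 479 lower against 104, or 342 higher and 253 lower with separate ones. RSL3 and LA had r = 0.423, below the simulated 0.457, and 0.0856 against separate DMSO libraries, with covariance 0.0392 against 0.0265, 15 higher genes shared against 1.42 and 2 lower against 0.136, or 7 higher and 0 lower with separate ones. For CLA18:2 and CLA18:3 the covariance was 0.216 against 0.0279. In RSL3+CLA18:2 and CLA18:3, r was 0.601, simulated 0.232 and 0.483 with separate ones, with covariance 0.215 against 0.0293, 1967 higher genes shared against 582 and 1451 lower against 453, or 1444 higher and 910.2 lower with separate ones. Among simulated unchanged groups no gene was called in both members of a pair.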

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

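All tests of the patterns weighed here were chosen after the result was seen except the count of transcripts lost in every CLA18:3 library and the correlation with transcript length, and the splits of the libraries were also chosen afterwards.

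Single libraries stood apart from the other 3 of their group by Dixon's gap test in 20 of 266 tests, where chance gives about 1 in 20, or 13.3. Mitochondrial mRNA took 0.548% in RSL3 replicate 4 (95% Wilson interval 0.544 to 0.551) and 1.68% in RSL3+CLA18:2 replicate 3 (95% Wilson interval 1.67 to 1.68). In CPM, RSL3 replicate 4 stood apart for HMOX1 (156), CHAC1 (5.75) and TXNRD1 (508), and CLA18:2 replicate 1 for GCLM (261). So did RSL3+LA replicate 3 (75.7) and LA replicate 3 (81.6) for GPX4 and LA replicate 2 for ACSL4 (182). DMSO replicate 4 (1135) and RSL3+CLA18:2 replicate 4 (1236) did for TFRC. Further ones were LA replicate 4 for FTH1 (264) and ANGPTL4 (2.53) and CLA18:3 replicate 1 for ANGPTL4 (0.0978). So were DMSO replicate 2 for ASNS (1.11) and replicate 1 for PLIN2 (0.0526) and ANGPTL4 (0.368). So were RSL3+CLA18:2 replicate 1 for CPT1A (54.4) and HMGCS1 (88.1) and replicate 4 for FADS2 (84.9).

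The log2 response to RSL3 differed with LA for 4 genes by the interaction test, all lower: HMOX1 (-1.45), SLC7A11 (-0.76), DDIT4 (-1.61) and NPC1 (-0.39). It differed with CLA18:2 for 580 genes. Named genes with a higher response there were ATF3 (0.65), GGNBP2 (4.23), FOSB (2.06), TLL1 (1.5), FOS (1.40) and PXMP2 (1.13), and with a lower one HMOX1 (-1.09), CHAC1 (-1.14), SLC7A11 (-1.22), TXNRD1 (-0.43), FTH1 (-0.39), DDIT3 (-1.44), TRIB3 (-0.51), HSPA5 (-0.61), CDKN1A (-0.24), CXCL8 (-1.36), OSGIN1 (-0.82), AKR1C1 (-2.97), HSPA6 (-2.96), GCNT3 (-2.82), DDIT4 (-2.26) and NMRAL2P (-1.98). Between CLA18:2 and LA it differed for 593 genes, higher for ATF3 (1.02), SCD (0.27), FADS1 (0.26), INSIG1 (0.34), RMRP (9.16), FOS (1.94), FOSB (1.87), TLL1 (1.58) and VSIG2 (1.40), and lower for SLC7A11 (-0.45), TXNRD1 (-0.23), DDIT3 (-1.19), TRIB3 (-0.31), HSPA5 (-0.41), CDKN1A (-0.26), OSGIN1 (-0.56), SDCCAG8 (-2.61), GCNT3 (-2.50), CORO6 (-1.76), HSPA6 (-1.62) and TRPV1 (-1.52). GGNBP2, RMRP and SDCCAG8 jump between libraries, so their values are uncertain, as are those of the paralogs AKR1C1 and HSPA6 and of the pseudogene NMRAL2P.

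Fewer genes were detected with CLA18:3 than with DMSO, 18686 to 20465 against 22651 to 22897 at a common total. A lower total count is excluded, since at that total the highest CLA18:3 library less the lowest DMSO library gave -2186. Among 14935 genes with a DMSO mean of at least 10 counts, a loss of the same transcripts in every library is excluded, as 0.610% of those at 0 in a CLA18:3 library (3 of 492) were at 0 in all 4, and 387 were at 0 in 1 only. For genes with fewer counts such a loss stays open. Fewer distinct molecules behind the reads and more variable cultures cannot be told apart, since the median variance to mean ratio of replicates, 4.10 with CLA18:3 and 1.13 in DMSO for genes with 10 to 40 counts, holds both.

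The share of mitochondrial mRNA fell in a low and a high range within groups. The Wilson intervals of the lowest and highest library were apart in all 7 groups, shares differed by up to 6.37-fold within a group, and 5 groups had libraries of the same treatment on both sides of 0.8%. Recovery by transcript length stays open, because the median correlation across 13894 genes was -0.0960, with groups from -0.247 to -0.00320, and genes are not independent replicates.

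Mitotic and DNA replication genes were higher in RSL3+CLA18:2 than in CLA18:2, by a median of 0.38 over 56 genes, with 0.37 to 0.38 without single libraries. CLA18:2 had -0.51 against DMSO and the combination -0.14. Libraries with few detected genes are excluded as the whole cause, as 0.363 was left without them with 2 libraries against 4. So is a shift shared by the separately listed samples, with 0.0220 for RSL3+LA against LA, but not one in CLA18:2 alone. Libraries with a low mitochondrial share cannot be told apart, since 0.377 rests on 1 library against 2. Weaker exposure to CLA18:2 in the combination also stays open, as NRF2 target medians had a ratio of 0.911 (0.902 to 0.960 without single libraries), and so does an effect of RSL3 itself.

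The libraries of each comparison were also split into other groups of the same sizes, fitting only those libraries. Chance is unlikely for each listed next, as only the real one of 35 splits gave as many genes. This is the lowest share possible, unadjusted over 12 comparisons. Other splits mix the treatments, so an effect itself lowers their counts. Against DMSO, real and highest other counts were 42 and 4 (RSL3), 2394 and 2 (LA) and 7383 and 0 (CLA18:2). They were 2366 and 1 (RSL3+LA), 5616 and 1 (RSL3+CLA18:2) and 5152 and 1 (CLA18:3). Against RSL3 they were 1590 and 1 (RSL3+LA) and 4421 and 41 (RSL3+CLA18:2). They were 1346 and 20 for RSL3+CLA18:2 against CLA18:2, 5540 and 0 for CLA18:2 against LA and 3327 and 1 for RSL3+CLA18:2 against RSL3+LA. For RSL3+LA against LA chance cannot be excluded, since 2 of 35 splits gave as many as the real 9, the highest other 10. For the interactions, labels were exchanged between libraries with and without RSL3, which also removes the RSL3 effect. These splits cannot decide whether chance explains an interaction. Of 100 splits, the real one included, 3 were as large for LA (real 4, highest other 24), 3 for CLA18:2 (real 689, highest other 1210) and 4 for the isomer (real 541, highest other 1014). Why other splits exceeded the real counts was not tested.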

How the results depend on the processing

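The fits with limma voom, without the libraries under 20000 detected genes or under 0.8% mitochondrial mRNA, and DESeq2 without independent filtering are tests chosen only after the results were seen.

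Of 1000 calls of named genes, DESeq2 ended 3 of 985, no low-count filter 31, only the groups compared 30 of 992, a replicate block 6, RLE scaling 5, limma voom 13, DESeq2 unfiltered 4 and leaving out a library 511 of 8896 calls. Without the low mitochondrial libraries 125 of 916 ended and 6 reversed, and without the libraries with few detected genes 27 of 526 ended. Of 221 calls of lists, the estimated correlation ended 69, no filter 6, leaving out a library 73 of 2080, a replicate block 1 and RLE 0, while the low mitochondrial libraries' removal ended 20 of 205 and reversed 4.

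Of 199 list tests that did not pass, no filter added 28, the low mitochondrial libraries' removal 8 with 3 more reversed, the removal of libraries with few detected genes 7 of 88, and leaving out a library 52 of 1952. Of 221 named genes not past the test, DESeq2 added 12 of 169, no filter 18, limma voom 13 and RLE scaling 1. RLE scaling and a replicate block moved no count of changed genes beyond 1.5 times.

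In RSL3 against DMSO the count was 112 with no low-count filter, 66 with DESeq2, 53 unfiltered, 150 with voom and 20 to 29 with a library left out. LA against DMSO had 2394 with only the groups compared and 2803 with voom, and RSL3+LA against DMSO 2608 with voom. RSL3+LA against LA had 164 with no filter, 37 with DESeq2, 26 unfiltered, 32 with voom and 4 to 9 with a library left out. The interaction with LA had 132 with no filter, 37 with DESeq2, 25 with voom, 3 to 5 with a library left out and 2 without the low mitochondrial libraries. The interaction with CLA18:2 had 889 with DESeq2, 1029 with voom, 400 to 663 with a library left out and 198 without those libraries. The isomer interaction had 203 without them and 374 to 591 with a library left out, and RSL3+CLA18:2 against CLA18:2 849 without them. Fewer libraries were fitted there, and for the other settings the cause was not tested.

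Correlations between responses moved where each response had its own DMSO libraries to these values: RSL3, 0.0856 with LA, 0.180 with CLA18:2, 0.0930 with RSL3+LA, 0.20 with RSL3+CLA18:2 and 0.157 with CLA18:3; LA, 0.349 with CLA18:2, 0.293 with RSL3+LA, 0.320 with RSL3+CLA18:2 and 0.190 with CLA18:3; CLA18:2, 0.337 with RSL3+LA, 0.638 with RSL3+CLA18:2 and 0.491 with CLA18:3; RSL3+LA, 0.319 with RSL3+CLA18:2 and 0.210 with CLA18:3 and RSL3+CLA18:2, 0.483 with CLA18:3. With no low-count filter, which adds genes with few counts, they were: RSL3, 0.471 with LA, 0.436 with CLA18:2 and 0.452 with RSL3+LA; LA, 0.469 with CLA18:2, 0.482 with RSL3+LA, 0.427 with RSL3+CLA18:2 and 0.389 with CLA18:3; CLA18:2, 0.449 with RSL3+LA, 0.503 with RSL3+CLA18:2 and 0.435 with CLA18:3; RSL3+LA, 0.416 with RSL3+CLA18:2 and RSL3+CLA18:2, 0.417 with CLA18:3.

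Reversals came without the low mitochondrial libraries, which left 1 RSL3+CLA18:2 library, assumed to vary like the other groups in the pooled fit. For mitochondrially encoded mRNAs as a list the adjusted p were 0.0408 in RSL3 against DMSO, 0.0969 in RSL3+CLA18:2 against DMSO, 0.211 against RSL3, 8.3e-07 against CLA18:2, 0.607 against RSL3+LA, 7.1e-05 in the interaction with CLA18:2 and 0.760 in that of the isomer. PLIN2 was -1.58 in RSL3+CLA18:2 against DMSO and -3.57 against RSL3. MT-ND5 was 0.078, MT-ND3 0.19 and MT-ATP8 0.077 in RSL3+CLA18:2 against DMSO, and MT-ND3 0.043 against RSL3+LA. The removal selects libraries by this share, so mitochondrial mRNAs move by construction, and for PLIN2, at 0 to 20 counts, the cause was not tested. Same-numbered libraries matched their own number in 9 of 28 cases, and depth limits genes near the floor.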
